A study of Homo sapiens with 2 samples.

How the data were processed

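Cultured smooth muscle cells of the human aorta were transfected with a lipid reagent, with 100 nM of siRNA against FOXM1 or of a non-targeting siRNA, and harvested after 48 h, per the labels' protocols. Total RNA was turned into biotin-labelled cRNA and hybridised to Affymetrix arrays, per the labels' protocols. There was 1 array per group and 2 arrays in all, so the number of arrays limits the precision and no test between the groups was possible. The array design is not named in the labels that were available.

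Both deposited tables hold the same 4584 probe sets with identical signals, and the largest difference between them was 0. The signal intensity per array is on a linear scale and was normalised by the authors, per the file headers, with the method and the target level not stated. MAS5 is named in the submitters' processing notes without a version or a role. The deposited fold change table also gives a standard error of each intensity and, per probe set, a signed fold with a lower and an upper bound and the difference of the signals, per the file headers. The deposited fold is the ratio of the higher to the lower signal, with a minus sign where the FoxM1 siRNA array was lower, and it matched the ratio of the deposited signals with a largest difference of 0.005. The confidence level of the bounds is not stated. The file's last lines say that these genes satisfied comparison filtering criteria, and give a median false discovery rate of 100% over 10 permutations for the 4584 listed. The criteria are not stated. In the values, the bound nearer to 1 was never below a size of 1.2, the difference of signals never below 100.1, and the fold never below 1.21. The table is therefore a list chosen for differing, with no detection calls and no probe sets that did not differ. No per-sample columns were left unused.

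Probe sets were named through the LocusLink identifier in the deposited table, or through the accession where the identifier gave no symbol. Both were matched to current symbols in a gene table of assembly GRCh38, used for names only. No coordinates are given because the files name no genome build. Of the 4584 probe sets, 4069 were named, and 515 got no symbol. The file gives no LocusLink identifier for 393 of the 4584. XIST and Y-linked genes were left out, and any probe sets of theirs count among the 515. For each gene the probe set with the highest mean log2 signal over both arrays was used, which gave 3040 genes. The value of a gene is the log2 of the FoxM1 siRNA signal over the control siRNA signal, both as deposited, with no further scaling. The planned filter on low signals was for tables of more than 15000 probe sets and was not applied.

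Genes were counted by a rule of size, at least 2-fold higher or lower, which is not a test. A total of 28 gene lists, written before the data were examined, cover FOXM1 targets, the cell cycle, smooth muscle functions, stress and markers of other cell types. For the 17 lists with at least 5 members in the table, the median log2 ratio was set against 10000 random lists of the same size, drawn from the listed genes and matched on mean log2 signal in 20 bins. A list whose median lay outside the central 95% of these was called apart from random lists. This describes these 2 arrays and is no test of the treatment, since genes are not replicates and genes of 1 pathway move together. The procedure was tested on simulated data first. The named genes followed a rule written before the data were examined. It took FOXM1, the 12 genes with the largest and the 12 with the smallest log2 ratio whose probe set lacks the suffix _x_at, the 3 members with the largest absolute log2 ratio in each list apart from random lists, and 2 in each other list with at least 5 members. Any other gene is named with the remark that it was chosen after its value was seen.

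The alternatives fixed before the data were examined were centring on the median log2 ratio, quantile normalization, removal of a loess trend (span 0.4) of the log2 ratio on mean signal, a filter at each array's median signal, no filter, an offset of 50 added before log2, the median over a gene's probe sets, probe sets without the suffixes _x_at and _s_at, size rules of 1.5-fold and 3-fold, and the other deposited table. Each array's median signal was taken over the listed probe sets, 737 on the control siRNA array and 780 on the FoxM1 siRNA array. The medians of the whole arrays are unknown. The planned comparison of 3' and 5' control probe sets was left out because the table holds 0 of them. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.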

Results

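FOXM1 is a forkhead transcription factor that is made in dividing cells and switches on genes for entry into mitosis. Vascular smooth muscle cells, the contractile cells of the arterial wall, can leave their contractile state and divide. In this experiment cultured smooth muscle cells of the human aorta received a small interfering RNA (siRNA) against FOXM1 or a non-targeting control siRNA, each at 100 nM. RNA was taken 48 h later and measured on Affymetrix expression arrays, with 1 array per group. The deposited table holds 4584 probe sets, each with a normalised signal per array, and 4069 of these were assigned to 3040 genes. The median signal over the listed probe sets was 737 on the control siRNA array and 780 on the FoxM1 siRNA array. Signals ran from 40.02 to 14308 on the control array and from 18.7 to 15618 on the FoxM1 siRNA array. The table is the submitters' selection of differing probe sets, so every listed gene differs by construction, and a gene outside the table has no value here. With 1 array per group no difference has a replicate check, no p-value was computed, and the number of arrays limits the precision.

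The first comparison asked how far the targeted transcript was reduced and how many genes differed with it. FOXM1 had a signal of 978 on the control array and 109 on the FoxM1 siRNA array, a log2 ratio of −3.17. It was 9.00-fold lower, the lowest log2 ratio among the 3040 listed genes. The authors' deposited table gives bounds of 7.83 and 10.57 for this fold, with no stated confidence level. Its 1 listed probe set carries the suffix _x_at, which marks probes that can bind other transcripts. Of the 3040 genes, 1939 were higher in the FoxM1 siRNA array and 1101 were lower. At the fixed size of at least 2-fold the balance turned over, with 42 genes higher and 232 lower. The median log2 ratio of all listed genes was 0.33. Subtracting it left 1520 genes higher and 1520 lower, of which 9 were at least 2-fold higher and 432 at least 2-fold lower. Because only differing probe sets were deposited, this median is no measure of an offset between the whole arrays, and the ratios below are as deposited.

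**Figure D1:**
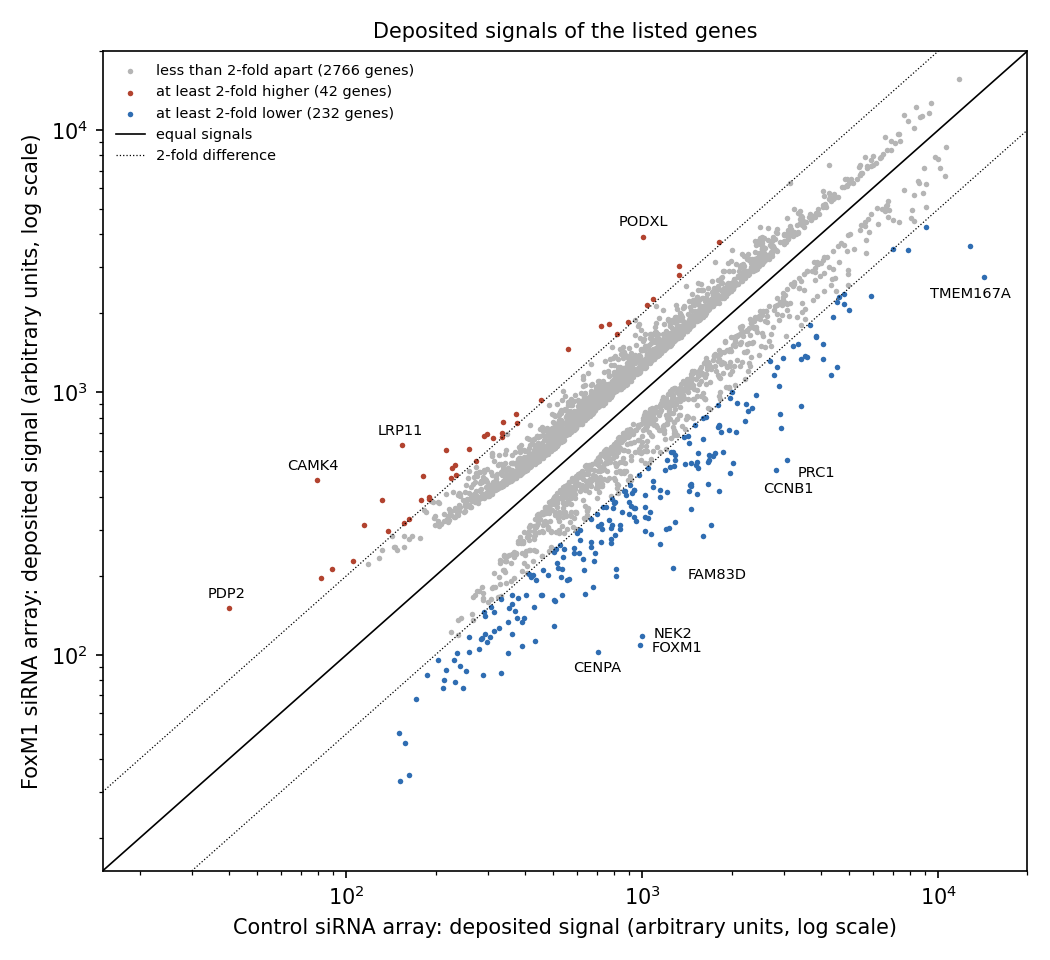
Each point is 1 of the 3040 listed genes, with its deposited signal on the control siRNA array (x axis) and on the FoxM1 siRNA array (y axis), both in arbitrary units on log scales. FOXM1 and NEK2 lie farthest below the line of equal signals, and 232 genes lie at least 2-fold below it against 42 at least 2-fold above it.

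Cell division genes were lower as a group, and the mitotic genes known as FOXM1 targets had the lowest median of the 17 lists compared. They encode the cyclin B kinase machinery, centromere proteins and the proteins that build the spindle midzone and part the daughter cells. Genes of the wider spindle and kinetochore apparatus, of DNA replication and of DNA repair had negative medians too. All 30 genes of the list of known FOXM1 targets in G2 and mitosis were in the table, all 30 were lower, and 25 of them were at least 2-fold lower. Their median log2 ratio was −1.59, and 0 of 10000 random lists of the same size and signal had a lower median. An alternative kept only genes at or above each array's median over the listed probe sets, which drops genes with lower signals after knockdown. Under this filter the median was −0.95, and that of the other spindle genes below was −0.84. NEK2, a centrosome kinase, went from a signal of 994 to 118 and was 8.43-fold lower, and its dimmer second probe set had a smaller difference, −1.79. The centromere histone CENPA was 6.88-fold lower, with signals of 707 and 103. PRC1, which bundles the microtubules of the spindle midzone, was 5.59-fold lower, with signals of 3087 and 552. CCNB1, the mitotic cyclin B1, was 5.58-fold lower, and its other listed probe set had a log2 ratio of −2.69. The phosphatase gene CDKN3 was 5.46-fold lower with signals of 1707 and 312. Within this list CDC25B had the smallest difference, at −0.44, while AURKB stood at −1.58 and PLK1 at −1.13. These 3 genes were chosen after their values were seen.

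Other spindle, kinetochore and cytokinesis genes were in the table for 32 of 38 members, and all 32 were lower, 21 of them at least 2-fold. The median of this list was −1.26, again below all 10000 random lists. The mitotic kinesin gene KIF14 was 4.06-fold lower, the spindle pole gene ASPM 4.05-fold lower and the abscission gene CEP55 3.75-fold lower. Dimmer probe sets of ASPM had log2 ratios of −2.34 and −0.74. DNA replication and S-phase genes were listed for 31 of 43 members, and all 31 were lower, with a median of −0.86 and 9 members at least 2-fold lower. Here 0 of 10000 random lists had a lower median, and the central 95% of them ran from −0.39 to 0.39. The replication licensing gene CDC6 was 2.67-fold lower, CCNE2, which encodes cyclin E2, 2.65-fold lower and MCM10 2.45-fold lower, but CCNE2 was under 2-fold after loess scaling and MCM10 after loess or quantile scaling. Of 14 listed DNA repair genes, 13 were lower and 1 was higher, with a median of −0.83, and 25 of 10000 random lists had a lower median. DTL was 2.85-fold lower, RAD51AP1 2.84-fold lower and BARD1 2.42-fold lower, whereas the damage kinase gene ATM was higher by a log2 ratio of 0.70. ATM was singled out after its value was seen. That value comes from an _x_at probe set, and the other listed probe set of ATM, an _s_at one, had 0.64. Replication-dependent histone genes were listed for only 5 of 18 members, and these did not follow as a group. Among the 5 listed members 4 were higher and 1 was lower, with a median of 0.38 that lay within the random range. H4C3 was 2.19-fold lower and H2BC21 1.63-fold higher, and the close similarity of histone gene copies leaves the source of these signals uncertain. These values do not show whether histone expression in S phase changed. Centring, quantile or loess scaling left every count of higher and lower members in these 5 lists in place, except that loess moved 1 more DNA repair gene to the higher side. Centring subtracts a positive value, so it could not move lower members to the higher side.

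The list of CDK inhibitors and p53 target genes had a positive median, and that of genes for the turnover of CDK inhibitors a negative one. CDK inhibitors block the cyclin kinases, and the ubiquitin ligase subunit SKP2 marks the inhibitors p21 and p27 for destruction. Among 15 listed CDK inhibitor and p53 target genes 14 were higher and 1 was lower, with a median of 0.48. Of 10000 random lists 17 had a higher median. GDF15 was 1.72-fold higher, from a probe set with the _x_at suffix, and the cell death gene BBC3 was 1.57-fold higher. CDKN1A, which encodes p21 and was picked after its value was seen, had signals of 9409 and 12659 and a log2 ratio of 0.43. The exception was the inhibitor gene CDKN2C, which was 2.47-fold lower. CDKN1A and CDKN2C were the CDK inhibitor genes listed, so these went in opposite directions, and the other members were p53 targets. In the list for turnover of CDKN1A and CDKN1B, 5 of 9 genes were in the table, 4 of them lower, with a median of −0.77. SKP2 was 3.70-fold lower from an _x_at probe set, and its other listed probe set was lower as well, at −1.31. FBXO5, an inhibitor of the anaphase-promoting complex, was 3.04-fold lower, and FBXW7 was 1.80-fold higher. The list was drawn up around SKP2 and its cofactors, and these values do not show that FBXO5 or FBXW7 acts on p21 or p27. Only 76 of 10000 random lists had a median below that of the turnover list. The directions in both lists were the same after centring, quantile and loess scaling, though centring could not have moved the lower members.

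**Figure D2:**
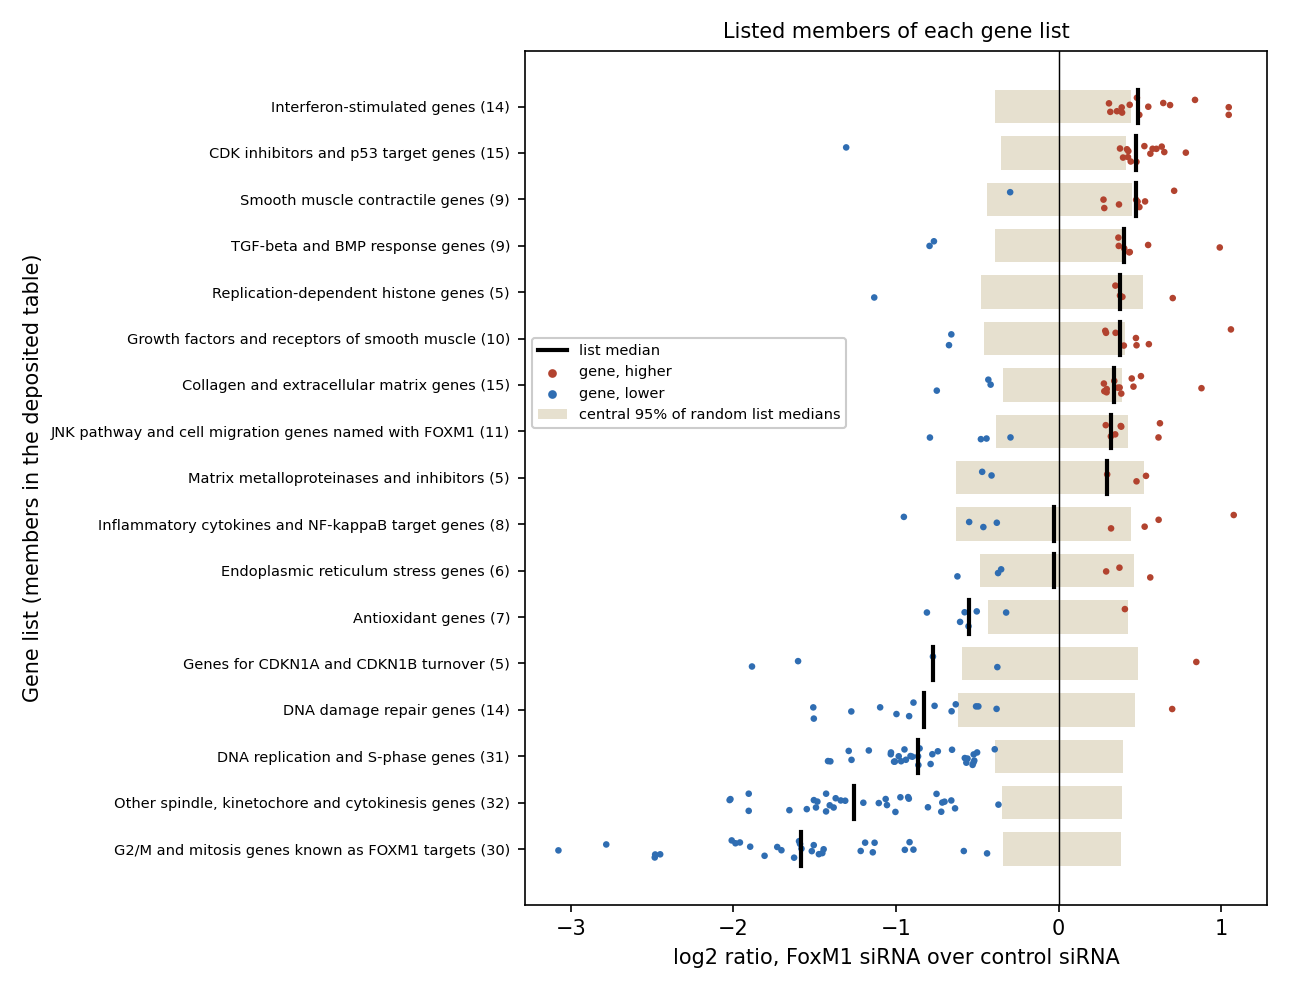
Points are the listed members of each gene list with at least 5 of them, at their log2 ratio of FoxM1 siRNA over control siRNA (x axis), black bars are list medians, and shaded bars span the central 95% of medians of 10000 random lists. The list of known FOXM1 targets has the lowest median, −1.59, and all of its 30 members lie below 0.

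Contractile, matrix, growth factor and TGF-beta genes each went both ways. Contractile genes encode the actin filaments and their regulators, which dividing smooth muscle cells make less of. Of 22 contractile genes 9 were listed, 8 higher and 1 lower, with a median of 0.48 and none at least 2-fold different in the probe set used. Random lists had a middle median of 0.32 and a central 95% from −0.44 to 0.45. The list median lay above this range, but no longer so under 4 alternatives. These were quantile scaling, loess scaling, the filter at each array's median signal, and leaving out _x_at and _s_at probe sets. After centring on the median of all listed genes, 6 contractile genes were higher and 3 lower. SYNPO2 was 1.64-fold higher, LMOD1 1.44-fold higher and the myosin kinase gene MYLK 1.41-fold higher. A dimmer probe set of SYNPO2 was 2.01-fold higher. ACTA2, smooth muscle actin, had a log2 ratio of 0.28 that turned to −0.05 after centring, CNN1 had 0.48, and CALD1 had −0.30, with −0.74 in a dimmer _x_at probe set. Those last 3 genes were chosen after their values were seen.

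Collagen and matrix genes were higher for 12 and lower for 3 of 15 listed members, and centring made this 8 and 7. Their median of 0.34 lay within the random range, with tenascin C (TNC) 1.84-fold higher and decorin (DCN) 1.68-fold lower. Among matrix metalloproteinases and their inhibitors 3 were higher and 2 lower, with a median of 0.30 that centring turned to −0.03. TIMP3 was 1.45-fold higher and MMP3 1.39-fold higher. Growth factors and receptors gave 8 higher and 2 lower genes, or 6 and 4 after centring, with a median of 0.38. The PDGF receptor gene PDGFRB was 2.08-fold higher, a size that was under 2-fold after centring, quantile or loess scaling, and the hepatocyte growth factor gene HGF was 1.60-fold lower, with a log2 ratio of −0.67 that was −0.04 after loess. TGF-beta and BMP response genes were higher for 7 and lower for 2 of 9 members, with a median of 0.40. INHBA, the activin subunit, was 1.99-fold higher and the ligand TGFB2 1.73-fold lower. In the list of JNK pathway and migration genes 7 were higher and 4 lower, or 5 and 6 after centring, with a median of 0.32 that centring turned to −0.01. MAPK8 was 1.73-fold lower and PTK2 1.54-fold higher. The medians of these 5 lists were not apart from random lists.

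Interferon-stimulated genes, which double-stranded RNA can induce, were all higher among the 14 listed of 35. Their median was 0.49, and 50 of 10000 random lists had a higher one, though it was within the random range when only genes at or above each array's median signal were kept. MX1 and IFIT1 were each 2.06-fold higher, and IFI6 was 1.79-fold higher. After centring 12 of the 14 remained on the higher side. MX1 and IFIT1 were under 2-fold after centring and also with an offset of 50. Antioxidant genes went the other way, with 6 of 7 listed members lower and a median of −0.55, below which lay 77 of 10000 random lists. The cystine transporter gene SLC7A11 was 1.75-fold lower, TXN 1.52-fold lower and PRDX3 1.49-fold lower, while SOD2, named after its value was seen, had a log2 ratio of 0.41. Inflammatory and NF-kappaB target genes were split, 4 higher and 4 lower, or 3 and 5 after centring, with a median of −0.03 and a mean of 0.02. The chemokine gene CCL7 was 2.11-fold higher, though under 2-fold after centring or with an offset of 50, and CXCL3 was 1.93-fold lower. Endoplasmic reticulum stress genes were split 3 and 3, or 2 higher and 4 lower after centring, with a median of −0.03. HSP90B1 was 1.54-fold lower from an _x_at probe set, and DDIT4 was 1.48-fold higher.

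Genes outside the cell cycle lists were also among the largest differences. FAM83D, which places a kinase on the spindle, was 5.92-fold lower, and ARL6IP6 was 5.66-fold lower, although its other listed probe set had a log2 ratio of only −0.67. DEPDC1 was 4.34-fold lower with signals of 1150 and 265. TMEM167A, a small Golgi membrane protein gene, had the highest control signal in the table, 14308, and was 5.22-fold lower, for which the authors' deposited table gives bounds of 3.08 and 17.01. The glycosyltransferase gene GALNT7 was 4.32-fold lower, and ZFAND4 was 4.68-fold lower from a signal of only 163. ZFAND4 came to a log2 ratio of 0.00 after loess scaling. That trend was fitted to listed probe sets only, and each dim one among them differs strongly. Loess values of dim genes therefore cannot separate scaling between the arrays from the selection of the list. On the higher side CAMK4, a calcium-dependent kinase gene, went from 79.4 to 464 and was 5.84-fold higher. Its log2 ratio of 2.55 became 3.39 after loess scaling and 1.99 with an offset of 50. The authors' deposited table gives bounds of 3.27 and 26.73 for CAMK4. LRP11 was 4.07-fold higher, and the cell surface sialomucin gene PODXL was 3.90-fold higher with signals of 1007 and 3923. PDP2 was 3.75-fold higher from 40.02, the lowest control signal in the table. Its log2 ratio of 1.91 varied with the setting, at 2.71 after quantile scaling, 4.09 after loess and 1.15 with an offset of 50. Loess raised the ratios of both ZFAND4 and PDP2, so the fitted trend was negative at their low signals. The cause of that trend was not tested.

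Other large positive ratios belonged to genes of varied function. The placental growth factor gene PGF was 2.95-fold higher, the iron exporter gene SLC40A1 2.77-fold higher and APOOL 2.72-fold higher. The ephrin receptor gene EPHA4 was 2.65-fold higher, and its other 2 probe sets had log2 ratios of 0.93 and 0.97. NEFM, a neurofilament gene, was 2.61-fold higher, SYT11 2.49-fold, ADAMTS3 2.40-fold and the potassium channel subunit gene KCNAB1 2.38-fold. SYT11, ADAMTS3 and KCNAB1 were under 2-fold after centring. With an offset of 50 ADAMTS3 came to a log2 ratio of 0.90 and KCNAB1 to 0.91, while loess scaling gave them 2.71 and 2.58. The values of these dim genes thus moved both ways with the setting, and the loess trend carries the selection of the list. Loess also moved PGF from 1.56 to 2.16 and APOOL from 1.44 to 2.31.

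Several functions had too few listed genes for a comparison with random lists. The members named here were chosen after their values were seen. Of 19 cholesterol synthesis genes 4 were listed, with FDFT1 at −1.61 and NSDHL at −0.34 against INSIG1 at 0.58 and STARD4 at 0.42. Of 26 glycolysis and hypoxia genes 4 were listed, with ENO1 at −0.51, SLC2A3 at 0.73, BNIP3L at 0.47 and ADM at 0.41. The respiratory chain genes NDUFB3 and NDUFS3 had log2 ratios of −0.76 and −0.65. Among heat shock genes DNAJB4 had −0.76 and HSPA4 0.68, and among immediate early genes NR4A1 had 0.42 and NR4A2 0.82. The other forkhead genes listed were FOXD1 at 0.37 and FOXN3 at 0.34. Markers of other cell types were few. The endothelial gene KDR had 0.39, the fibroblast markers DCN, TCF21 and CD34 had −0.75, 0.40 and 0.59, and 0 leukocyte or epithelial markers were listed. None of the 27 ribosomal protein genes was in the table.

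Agreement between probe sets of 1 gene could be counted only among listed ones, since probe sets that did not pass the submitters' filter are missing. Of 751 genes with more than 1 listed probe set, 721 had all of them in 1 direction and 30 had them in opposite directions. The median gap between the highest and the lowest probe set of a gene was 0.12 on the log2 scale, and the 90th percentile was 0.58. All 72 genes at least 2-fold lower with more than 1 listed probe set had all of them lower, and all 8 at least 2-fold higher had all of them higher. Size was judged here on the probe set with the highest mean signal. A dimmer probe set could be over 2-fold lower while that one was higher, as in PPP3CB, with −1.31 and 0.37. PPP3CB was chosen after its values were seen. Of 28 lists, 17 had enough members for random lists, and 9 of these 17 were apart from them. Simulations shuffled the ratios among the 3040 genes and set lists of 15 genes against 1000 random lists each. Of unshifted lists 6.5% were apart, as were 16% of lists shifted by −0.5 and 100% of lists shifted by −1. Upward shifts were not simulated, so how often a higher list would be found is unknown. Lists within the random range are therefore not shown to be unaffected.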

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

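All alternatives were chosen before the data were examined. FOXM1 was lower under every alternative that gave it a value, and it had none with the filter at each array's median or without _x_at and _s_at probe sets, since its only listed probe set is an _x_at one that is dim after knockdown. The counts of genes at least 2-fold higher (42) and lower (232) became 9 and 432 after centring, 9 and 41 with the filter at each array's median (which leaves 1420 genes), 301 and 520 at 1.5-fold, and 4 and 59 at 3-fold. With 50 added to both signals 24 genes were at least 2-fold higher, as such an offset shrinks ratios of dim probe sets. The median of all genes (0.33) was 0.00 after centring, by construction, and 0.17 after loess. Quantile and loess scaling were also computed on the listed probe sets only, so they do not measure an offset or trend of the whole arrays. The filter likewise used medians of the listed probe sets, so genes it dropped need not be dim on the whole arrays. The contractile genes were no longer apart from random lists after quantile (0.39) or loess scaling (0.31), with the filter (0.38), or without _x_at and _s_at probe sets (0.48), nor were the interferon genes with the filter (0.39). The growth factor genes with the filter (0.44) and the TGF-beta genes after loess (0.33) became apart. The cause of these list changes was not tested. Of 91 list results under the alternatives that could alter a call, 84 kept it. These leave out no filter and the other deposited table, which both give the same values, and centring, which shifts a list and its random lists alike. For named genes 336 results differed in value from the main one, of which 306 kept their call, 21 went under 2-fold and 9 went over it. The other 277 were identical, among them each value under the filter at each array's median. No list apart from random lists and no named gene at least 2-fold different changed sign. Part of this was fixed in advance. An offset added to both signals cannot turn the sign of a gene. Subtracting 0.33 cannot turn a negative value or a rise of at least 2-fold. Among other list medians and named genes, centring turned the metalloproteinase (−0.03) and JNK (−0.01) medians and ACTA2 (−0.05), leaving out _x_at and _s_at probe sets turned the JNK median (−0.08), and the median over probe sets turned the inflammatory one (0.07). Unnamed genes were only counted. The filter and the probe set suffix left several lists under 5 members and many named genes without a value. The planned 3' to 5' control comparison was not run because the table holds no such probe sets. No paired analysis was possible because each group has 1 array, and no replicate could be left out. With no detection calls, signal over background is unknown, which limits dim genes most.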

Other observations

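Gene families outside the fixed lists were chosen after their values were seen, as were the tests below except those of probe sets in opposite directions. All 10 listed nucleoporin (NUP) genes, which encode the nuclear pore, were lower, with a median log2 ratio of −0.49 and NUP54 lowest at −1.59, whereas 63.8% of all listed genes were higher. Among centromere protein (CENP) genes outside the lists 8 of 9 were lower, with CENPU at −1.40, and CENPL was higher at 0.46. Of 8 kinesin genes outside the lists, 3 were lower, KIF18B at −1.94, KIF20B at −1.66 and KIFC1 at −0.75. The other 5 were higher, KIF3B at 0.80, KIF3C at 0.49, KIF7 at 0.41, KIF5C at 0.37 and KIF1B at 0.30, and after centring KIF1B was lower. All 7 listed potassium channel (KCN) genes were higher, with a median of 0.43, among them KCNAB1 at 1.25, KCNK2 at 0.67 and KCNJ8 at 0.66. The directions of the NUP, CENP and KCN genes were the same after centring, quantile and loess scaling. For genes that were already lower, centring could not change the direction. The 8 listed TBC1D genes were also all higher, with a median of 0.37, but after centring 6 of them were.

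Small differences were more often higher and large ones more often lower in the FoxM1 siRNA array. At a log2 size of at least 0.4 there were 1527 probe sets higher and 1265 lower. At least 0.5 in size were 863 and 1016, and at least 1 were 74 and 383. The offset that would balance both sides was 0.02 for a size of at least 0.4 and −0.27 for at least 1. These offsets follow from the same counts, so a constant scaling offset that adds to larger negative differences stays open. Lower expression of proliferation genes may account for part of the excess, as 62 of the 232 genes at least 2-fold lower are in the 6 proliferation lists and 0 of the 42 higher ones are. The other 169, FOXM1 aside, cannot be told apart between proliferation genes that the lists lack, off-target transcripts of the siRNA and other effects, because the lists are incomplete and the siRNA sequence is not given.

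The standard errors in the authors' deposited table are tied between the arrays. The product of signal and standard error was equal on both arrays within rounding in 100% of the 4584 probe sets. This argues against errors estimated from each array alone, which gave equal products in 0.109% of simulated probe sets. A candidate explanation is one multiplicative probe model fitted to these 2 arrays only. It gave equal products in 100% of probe sets simulated with 11 probes, which follows from the algebra of such a fit. With 1 array per group the deposited bounds cannot measure variation between cultures, whichever model gave them. Of the 1415 pairs of probe sets of 1 gene, 56.7% had bounds that did not overlap.

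In 30 genes the listed probe sets went in opposite directions. Examples picked after their values were seen are DIP2B, with log2 ratios of −2.75 and 0.32, and HSDL2, with −2.08 and 0.38. Dim probe sets may contribute, since the dimmest probe set of these genes had a median log2 signal 0.52 below that of the 721 genes whose probe sets agree, a difference of −0.52 with a 95% bootstrap interval from −0.90 to −0.25. Cross-hybridization may contribute too, as 33.3% of the 30 genes had an _x_at probe set against 19.3% of the 721. That share counts any _x_at probe set of a gene, whichever way it went. It was on the side of most probe sets in QKI, RARA and SCAF11, and on the other side in SAV1 and LIMK2. These examples too were picked after their values were seen. The number of probe sets per gene was not matched in either comparison. Neither value reached the size set in advance for or against its explanation, so both stay open, and no biological explanation was tested.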
